A study of Rattus norvegicus with 12 samples.

How the data were processed

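Gene expression was measured in whole urinary bladder from female Sprague Dawley rats of about 3 months, 6 sham-operated and 6 taken 10 days after a denervating operation in which the ganglia supplying the bladder were frozen on both sides. Total RNA was labelled with biotin and hybridised to 1 array per sample, so the data hold 12 arrays. Groups and replicate numbers were taken from the sample titles. The series also studied microRNA, which was not analysed here. Nothing in the labels says outright that each array came from a separate animal, so the p-values of single genes measure the spread between these samples. No scan date, array batch or operator is given in the sources used here, and a batch that followed the groups could not be examined.

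The values used are log2 expression values that the authors deposited as a table of 36685 probe sets by 12 arrays. Per the submitters' processing notes, they were made by RMA, which corrects background, quantile-normalizes the arrays and summarises the probes of each probe set, in Affymetrix Expression Console 1.4.1.46. The genome build and annotation behind the array are not given in the sources used here, and no coordinates are printed. The table carries no per-probe detection call, so background can only be judged from the brightness of a gene, and the number of arrays limits the precision. Medians of the deposited values lay between 5.82 and 5.90 on all 12 arrays. The values were tested as deposited, without further normalization, centring or filter on dim probe sets.

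Probe sets were named through the platform's gene table. It names 19086 probe sets and leaves 17599 unnamed here. Of the named ones, 575 carry several genes and were not used under a gene name, and 18511 carry 1 gene. Of the latter, 18394 were matched by gene identifier to a RefSeq gene table of assembly GRCr8, used for names only, and 117 were not matched and kept their listed symbol. No symbol needed updating (0 updated). For 291 genes with several probe sets, the one with the highest mean over the 12 arrays stood for the gene, which left 18166 genes. Genes of multigene families with close copies can share probes, and their values are uncertain in that respect.

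Denervated and sham arrays were compared gene by gene with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings, 1 coefficient for denervated minus sham, two-sided moderated test), with Benjamini-Hochberg adjustment over all 18166 genes and a threshold of 0.05 on the adjusted p. "Called", "rose" and "fell" refer to that threshold. Every adjusted p of a gene comes from this limma fit unless stated. Changes are log2 differences of the group means with their standard errors.

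Before the data were examined, 39 gene lists with 1148 distinct measured genes were fixed for smooth muscle, matrix, nerve, urothelium, blood and immune cells, metabolism and signalling, along with the tests, the alternatives and the rule for naming genes. Each list was tested with limma's camera against all other genes, with the preset inter-gene correlation of 0.01, two-sided and adjusted over the 39 lists. With that preset its p-values set genes against genes and do not by themselves measure the spread between samples. For each list the number of members past the threshold is given over all genes tested and adjusted over the list alone. Camera was also run with an estimated correlation, and fry, which asks whether the genes of a list move on balance in 1 direction without comparing them with other genes, was run as an alternative. A gene may belong to several lists.

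Genes were named by this rule: the 15 largest rises and 15 largest falls among called genes whose 6 values in one group lay wholly outside the 6 of the other, up to 4 called members of each list with the largest absolute change, and a short set of bladder, muscle and matrix genes named whatever their values. Symbols with prefixes or endings fixed beforehand, those of placeholders and of families such as olfactory receptors and immunoglobulins, were to be passed over, and 0 genes were. Other families with close copies were not on that list, and some of their members are pointed out where they are named. Of the set named whatever their values, genes such as Acta2 and Gapdh were not tested here, because no probe set used under a gene name carries that symbol alone, and Ctgf was measured under its present symbol Ccn2. Other members of the lists are named as examples, and those were chosen after their values were seen.

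Alternatives were a further quantile normalization, centring each array on its median, keeping only genes brighter than the median gene or leaving out the dimmest 25%, eBayes with trend and robust settings, array weights, an exact rank-sum test per gene, a test against a change of at least 1.2-fold (limma's treat), the mean of a gene's probe sets, all probe sets with or without a name, the replicate number as a block, and leaving out each of the 12 arrays in turn. The counts of list members without denervated replicate 2 and without sham replicate 3 were added after these arrays were seen to stand apart.

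The scripts were tested on simulated data with the real genes' means and spreads, genes drawn independently of each other, 6 arrays against 6 and 200 changed genes among 18166. The limma fit called 71.6% of genes changed by 0.5 on the log2 scale, 92.5% of those changed by 1 and 98.5% of those changed by 2, with 13 false calls. Camera called 2 of 2 shifted sets and 0 of 18 sets that were not shifted. Since the simulated genes were independent, this does not show how often camera calls unshifted lists of correlated genes. The exact rank-sum test recovered 0% at each size in the simulation, since so few changed genes cannot pass the adjustment with 6 arrays a group. Bootstrap intervals used 1000 draws and the regroupings of arrays were drawn with seed 20. Tables were read and figures drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.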

Results

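The series compared 6 urinary bladder samples from sham-operated rats with 6 samples taken 10 days after the bladder had been denervated, to learn which genes respond to the loss of innervation. The labels describe the tissue as almost wholly smooth muscle. Expression of 18166 genes was read on 12 arrays, 1 per sample, with array medians between 5.82 and 5.90 on the log2 scale. Correlations between arrays across genes, which are not independent replicates, had a median of 0.994 among sham arrays and 0.986 among denervated arrays. Denervated replicate 2 stood apart from its group. On the first principal component, which held 58.0% of the variance, it lay at -5.84, against 25.9 to 42.5 for the other 5 denervated arrays and -30.2 to -22.5 for the 6 sham arrays.

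Lists of extracellular matrix, cell cycle, macrophage and interferon response genes were called higher after denervation, and lists of urothelial, Schwann cell, mitochondrial and contractile genes lower, the last with 15 of 26 members lower. These calls rest on a preset correlation between genes and were lost with an estimated correlation, with adjusted p of 0.170 to 0.481. The study drew attention to Cthrc1, a secreted protein with a short collagen-like repeat, in the denervated bladder. Here Cthrc1 rose 10.6-fold, by 3.41 ± 0.31 on the log2 scale (SE, n = 6 per group, adjusted p = 3.73e-05). In all, 5216 of 18166 genes were called (28.7%), 2153 higher and 3063 lower. Among changes of at least 2-fold the balance was the other way, with 527 genes higher and 156 lower. The values of the groups did not overlap at all for 2425 genes (13.3%), against 0.216% by chance. When changes smaller than 1.2-fold were to be excluded by the test itself, 756 genes were higher and 496 lower, so that 60.4% of the calls were higher, against 41.3% of the calls against no change.

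**Figure D1:**
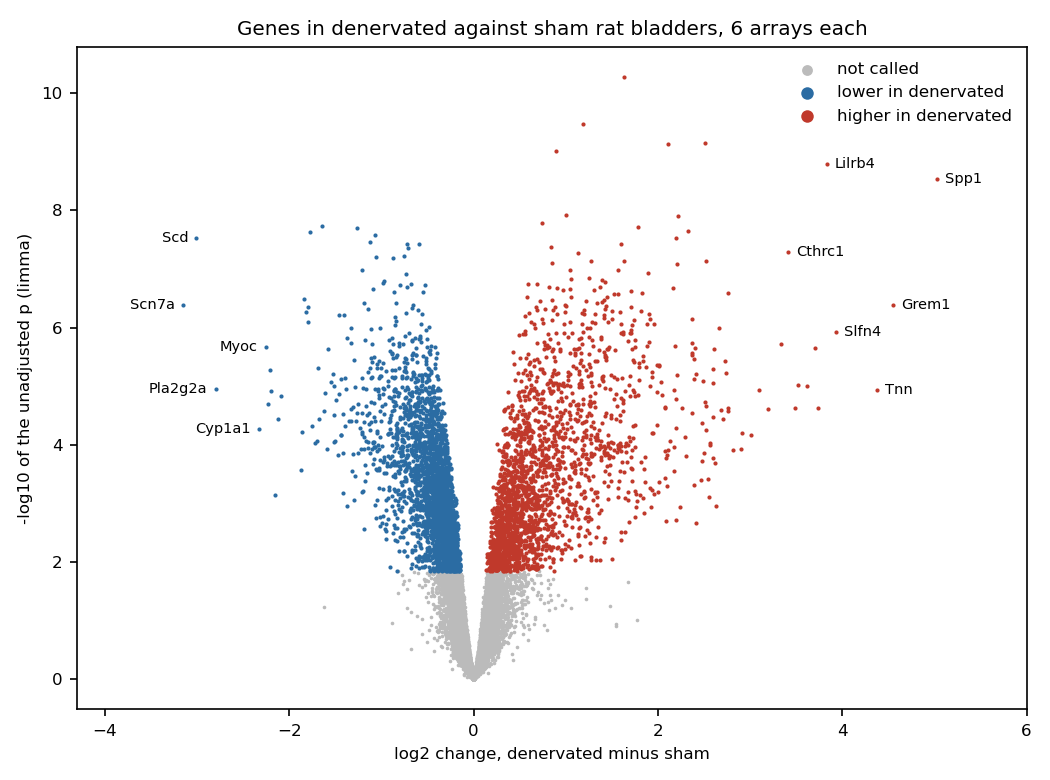
Each point is 1 of the 18166 genes, with its log2 change (denervated minus sham, 6 arrays each) on the horizontal axis and the negative log10 of its unadjusted limma p on the vertical axis. The 2153 called rises reach further from 0 than the 3063 called falls, with Spp1 at 5.03 and Scn7a at -3.15 at the ends. The sham mean of Spp1 lay below the array medians, so the size of its rise is uncertain. Whether background in dim genes shaped the larger reach of the rises was not tested.

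The largest rise was that of Spp1 (osteopontin, a secreted matrix phosphoprotein), by 5.03 ± 0.36 or 32.6-fold (adjusted p = 7.58e-06). It was followed by Grem1, a secreted antagonist of bone morphogenetic proteins (4.55 ± 0.49), and Tnn, a tenascin of the extracellular matrix (4.38 ± 0.64). Cilp, a cartilage matrix protein, rose by 3.52, Prss35, a secreted protease-like protein, by 3.71, and Olr1, a scavenger receptor for oxidised lipoprotein, by 3.62. The interferon-induced genes Mx1 (3.74) and Irf7 (3.19) and the chemokines Cxcl13 (3.34), which attracts B cells, and Cxcl9 (3.01), which attracts T cells, were also among the 15 largest rises. The others were Slfn4 (3.93), Lilrb4 (3.83), Ly49si1 (3.48) and Fcgr3a (3.09), which belong to immune gene families with close copies, so that their probes may share signal. SEs of these 15 genes lay between 0.26 and 0.64, and all adjusted p were at most 0.00118. By the rule for naming them, all 6 denervated values lay above all 6 sham values, so genes with overlapping values were left out. Grem1 stood at 7.83 in denervated replicate 2 and between 10.18 and 11.38 in the other 5. Sham means of Spp1, Tnn, Lilrb4, Mx1, Prss35, Olr1, Ly49si1, Fcgr3a and Cxcl9 lay below the array medians, so these genes were dim in sham bladders. Their signal over background there is unknown, so the sizes of their rises, the 32.6-fold of Spp1 included, are uncertain. Sham means of Grem1, Slfn4, Cilp, Cthrc1, Cxcl13 and Irf7 lay above the array medians.

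Scn7a, a sodium channel gene of Schwann cells, fell most (-3.15 ± 0.34, adjusted p = 9.23e-05). Further genes of nerve among the 15 largest falls were Cdh19 (-2.21), a cadherin of the Schwann cell lineage, Nefl (-2.23), the light chain of neurofilament, and Gpm6a (-1.85), a neuronal membrane glycoprotein. Scd, which makes monounsaturated fatty acids (-3.01 ± 0.26), Pla2g2a, a secreted phospholipase (-2.80 ± 0.41), and Cyp1a1, a cytochrome P450 of xenobiotic metabolism (-2.33 ± 0.40), fell too. Krt20, a keratin of the superficial urothelial cells, stood at -1.80 and Sfrp5, a secreted Wnt antagonist, at -1.77. The remaining members were Myoc (-2.25), Mamdc2 (-2.19), Slitrk6 (-2.09), Spock2 (-1.86), Car14 (-1.82) and Alpg (-1.80). All adjusted p of the 15 were at most 0.00112. By the same rule all 6 denervated values lay below all 6 sham values. Falls with overlapping values were left out, such as that of Thrsp (-1.87), which was larger than that of Spock2. In denervated replicate 2 these falls were smaller for Pla2g2a (11.84, against 8.53 to 9.74 in the other 5), Cdh19 (6.92, against 4.48 to 5.15) and Car14 (5.78, against 4.34 to 4.67).

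Of the 39 gene lists, camera called 16 higher and 7 lower. With an estimated correlation between genes 0 of them were called higher and 0 lower. Every call of these lists thus rests on the preset correlation, and the adjusted p with an estimated correlation stands beside each. No list was chosen by the study on these samples. Under the other alternatives run with camera, 18 of the 23 called lists stayed past the threshold throughout, with adjusted p of at most 0.0195, and the 5 that did not are named where they are described.

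Genes of the extracellular matrix rose. Of 40 matricellular and other matrix proteins, 27 rose, 3 fell and 10 were not called (29 and 3 adjusted over the list alone; camera adjusted p = 8.86e-13, and adjusted p = 0.235 with an estimated correlation). After Spp1, Tnn and Cthrc1 came Eln, the gene of elastin (2.51 ± 0.39), and Ccn2, connective tissue growth factor (2.29 ± 0.41). Fibronectin (Fn1, 1.60) and versican (Vcan, 2.17) rose too, while Hapln1 (-0.84), Efemp1 (-0.75) and Tgfbi (-0.33) fell. Of 26 collagens, 19 rose, 2 fell and 5 were not called (19 and 2 adjusted over the list alone; camera adjusted p = 1.96e-09, and adjusted p = 0.235 with an estimated correlation). Col11a1 (2.62 ± 0.52), Col12a1 (1.64 ± 0.30), Col8a1 (1.57 ± 0.36) and Col18a1 (2.75-fold) rose most. The major fibrillar genes Col1a1 (0.60 ± 0.13, 1.52-fold) and Col3a1 (0.49 ± 0.10) rose too. Col4a5 (-0.37) and Col17a1 (-0.29) fell. Without sham replicate 1, 2 or 5, 1 collagen fell, and without sham replicate 3, 4 or 6 or denervated replicate 3, 4, 5 or 6, 0 did.

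Genes that modify or degrade matrix rose too. Of 27 genes for collagen processing and cross-linking, 19 rose, 1 fell (P3h2, -1.11) and 7 were not called (23 and 1 adjusted over the list alone; camera adjusted p = 5.34e-12, and adjusted p = 0.235 with an estimated correlation). P4ha3, a prolyl hydroxylase subunit (2.48 ± 0.41), and the cross-linking oxidases Lox (2.03 ± 0.29), Loxl1 (1.91 ± 0.24) and Loxl2 (1.66 ± 0.33) led the list. Among 34 matrix proteases and inhibitors 23 rose, 2 fell and 9 were not called (27 and 2 adjusted over the list alone; camera adjusted p = 2.36e-11, and adjusted p = 0.211 with an estimated correlation). Both the macrophage elastase Mmp12 (2.68 ± 0.43) and the inhibitor Timp1 (1.80 ± 0.24) rose, as did Adam12 (2.37) and the gelatinase Mmp9 (1.72), while Mmp16 (-1.02) and Timp4 (-0.38) fell. In denervated replicate 2 the mean over the collagens lay 0.18 above the sham mean and that over collagen processing genes 0.14, against 0.35 to 1.07 and 0.43 to 1.21 in the other 5 denervated arrays.

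Proliferation genes rose. Of 54 cell cycle genes, 48 rose, 1 fell and 5 were not called (49 and 1 adjusted over the list alone; camera adjusted p = 5.62e-20, and adjusted p = 0.235 with an estimated correlation). The proliferation antigen Mki67 rose by 2.59 ± 0.50, the ribonucleotide reductase subunit Rrm2 by 2.50 ± 0.47, Ckap2 by 2.18 ± 0.45 and the topoisomerase Top2a by 2.10 ± 0.46. Ccnd1, which encodes cyclin D1, fell by 0.56. The mean over this list lay 1.12 to 1.47 above the sham mean in 5 denervated arrays and 0.08 above it in denervated replicate 2. Sham replicate 3 lay at 0.69, against -0.20 to 0.05 in the other 5 sham arrays. Without denervated replicate 2, 50 members rose, and without sham replicate 3, 46 did.

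Genes of the secretory pathway rose by smaller amounts. Of 36 genes for folding and stress in the endoplasmic reticulum, 21 rose, 0 fell and 15 were not called (23 and 0 adjusted over the list alone; camera adjusted p = 6.09e-11, and adjusted p = 0.235 with an estimated correlation). Sdf2l1 (0.76 ± 0.14), the translocon subunit Sec61b (0.69 ± 0.16), the vesicle coat gene Sec24d (0.66 ± 0.13) and the chaperone Hspa5 (0.61) were among them. The mean over this list was 0.06 in denervated replicate 2, against 0.32 to 0.53 in the other 5 denervated arrays and up to 0.08 in sham arrays. Kdelr3, a receptor that returns proteins to the endoplasmic reticulum, rose by 0.76 ± 0.23, and its call was lost without sham replicate 1 (adjusted p = 0.0550), sham replicate 2 (0.0541) or denervated replicate 5 (0.0566). Of 35 genes for amino acid transport, serine synthesis and tRNA charging, 9 rose, 1 fell and 25 were not called (9 and 1 adjusted over the list alone; camera adjusted p = 0.000206, and adjusted p = 0.481 with an estimated correlation). The fry test did not call it (adjusted p = 0.0843), and its mean was -0.02 in denervated replicate 2 and 0.18 to 0.65 in the other 5. The mitochondrial folate enzymes Aldh1l2 (1.41 ± 0.26) and Mthfd2 (1.05 ± 0.27), the cystine carrier Slc7a11 (1.02 ± 0.14) and the proline synthesis enzyme Aldh18a1 (0.97 ± 0.19) rose most, and 15 members rose without denervated replicate 2. Without denervated replicate 3 or 6, 2 fell. Of 30 genes for ribosome biogenesis and polyamine synthesis, 28 were not called. Srm, spermidine synthase, rose by 0.56, Amd1, of the same pathway, fell by 0.55, and adjusted over the list alone 0 rose and 1 fell (camera adjusted p = 0.325, and 0.0412 without denervated replicate 6). Falls numbered 2 without sham replicate 1, 3 without denervated replicate 2 and 4 without denervated replicate 6.

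Markers of immune cells rose in the denervated bladders. Of 28 monocyte and macrophage genes, 25 rose, 0 fell and 3 were not called (25 and 0 adjusted over the list alone; camera adjusted p = 3.29e-22, and adjusted p = 0.170 with an estimated correlation). The lysosomal protein Cd68 rose by 2.20 ± 0.19, lysozyme (Lyz2) by 2.11 ± 0.14, Ms4a6a by 2.17 ± 0.40 and Cybb, a subunit of the phagocyte oxidase, by 1.78 ± 0.15. Lgals3 (-0.14), Marco (0.16) and Cd163 (0.21) were not called. Denervated replicate 2 had a mean over this list of 0.77 above the sham mean, against 0.96 to 1.63 in the other 5.

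Lymphocyte genes followed with 19 of 29 higher, 0 lower and 10 not called (22 and 0 adjusted over the list alone; camera adjusted p = 4.32e-10, and adjusted p = 0.211 with an estimated correlation). Jchain, the joining chain of secreted antibodies, rose by 2.92 ± 0.51, and the natural killer and T cell genes Klrk1 (2.31 ± 0.44), Nkg7 (1.31 ± 0.30) and Cd8b (1.30 ± 0.25) rose as well, whereas the B cell genes Ms4a1 (0.08) and Cd79a (0.02) were not called. Of 23 mast cell and granulocyte genes, 4 rose and 2 fell (5 and 2 adjusted over the list alone), and the list was not called (camera adjusted p = 0.0586). It was called without sham replicate 1 (adjusted p = 0.0394), sham replicate 2 (0.0384) or denervated replicate 3 (0.0228) and after median centring (0.0426), and 7 members rose and 3 fell without denervated replicate 2. Csf3r, the receptor of granulocyte colony-stimulating factor, rose by 1.51, the mast cell tryptase Tpsab1 by 0.59 and S100a8 by 0.63, and the prostaglandin synthase Hpgds fell by 0.86. S100a8 was dim, with means of 3.53 in sham and 4.16 in denervated arrays.

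The interferon response list had 28 of 32 members higher, 0 lower and 4 not called (29 and 0 adjusted over the list alone; camera adjusted p = 2.31e-16, and adjusted p = 0.235 with an estimated correlation). Besides Mx1 and Irf7, the ubiquitin-like protein Isg15 rose by 2.90 ± 0.54 and Ifit3 by 2.62 ± 0.63. The 6 denervated arrays differed widely in this list, with means from 0.54 above the sham mean in replicate 3 to 3.23 in replicate 6. Of 38 cytokines and chemokines, 17 rose, 2 fell and 19 were not called (17 and 2 adjusted over the list alone; camera adjusted p = 5.87e-05, and adjusted p = 0.228 with an estimated correlation). After Cxcl13 and Cxcl9 came Ccl12 (2.39 ± 0.52) and Cxcl10 (2.20 ± 0.57), while the eosinophil chemoattractant Ccl11 fell by 2.15. Without sham replicate 1, 2, 4, 5 or 6 or denervated replicate 1 or 5, 1 member fell. The mean over this list was 1.28 in denervated replicate 6 and 0.32 to 0.66 in the other 5.

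**Figure D2:**
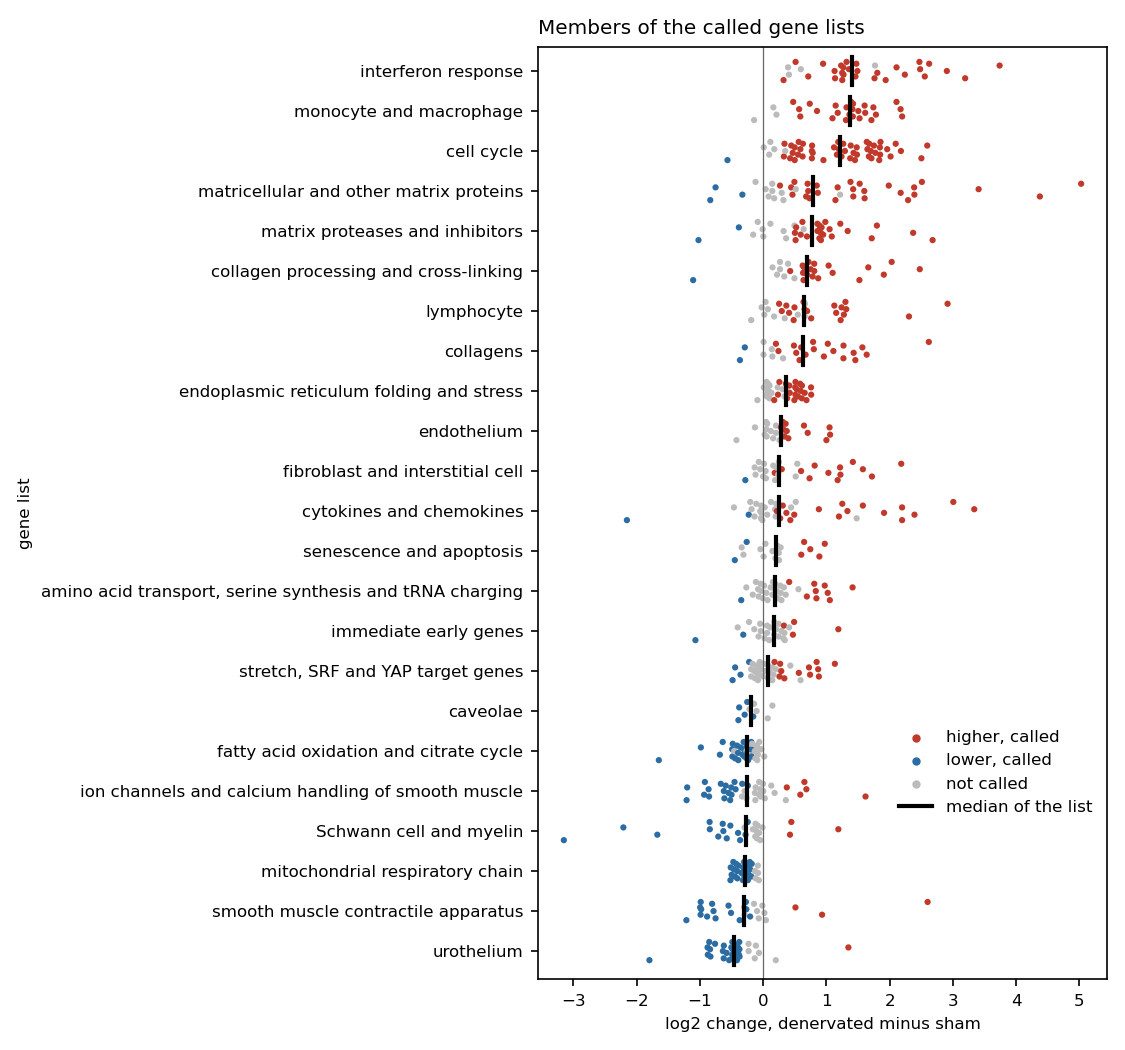
Log2 changes (denervated minus sham, horizontal axis) of the measured members of the 23 gene lists called by camera are drawn as points, red where a member rose past the threshold, blue where it fell and grey where it was not called, with a black bar at the median of each list. Medians run from 1.41 for the interferon response to -0.46 for the urothelium, and 0 of 34 respiratory chain genes lie among the called rises.

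Genes of vessels and connective tissue cells rose in part. Of 25 endothelial genes, 12 rose, 0 fell and 13 were not called (13 and 1 adjusted over the list alone; camera adjusted p = 9.73e-08, and adjusted p = 0.170 with an estimated correlation). Sox18 (1.06 ± 0.11), the apelin receptor Aplnr (1.05 ± 0.10), vascular cadherin Cdh5 (1.00 ± 0.08) and Erg (0.70 ± 0.13) rose, and Vwf (0.20) was not called. Without denervated replicate 4, 1 member fell. Of 29 genes of fibroblasts and interstitial cells, 13 rose, 1 fell (Tcf21, -0.28; 0 without sham replicate 1, 3 or 5 or denervated replicate 3, 5 or 6) and 15 were not called (15 and 1 adjusted over the list alone; camera adjusted p = 3.30e-06, and adjusted p = 0.235 with an estimated correlation). Complement C3 (2.18 ± 0.27), Fndc1 (1.72 ± 0.32), the fibroblast activation protein Fap (1.58 ± 0.34) and Ly6c (1.42 ± 0.42), which has close copies, rose most. The mean over the fibroblast list was 0.04 in denervated replicate 2 and 0.46 to 0.77 in the other 5.

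Genes of Schwann cells fell. Of 27 Schwann cell and myelin genes, 14 fell, 3 rose and 10 were not called (15 and 3 adjusted over the list alone; camera adjusted p = 0.000715, and adjusted p = 0.211 with an estimated correlation). After Scn7a and Cdh19, Art3 fell by 1.67 ± 0.28 and S100b, a calcium-binding protein of glia, by 0.84 ± 0.13. Mbp was called at -0.24, and Pmp22 (-0.13) and Mag (-0.01) were not called. Egr2, a transcription factor of myelination that is also an immediate early gene, rose by 1.19 ± 0.23, and Cnp (0.45) and Cadm4 (0.42) rose too. The mean over this list was -0.20 in denervated replicate 2 and -0.54 to -0.45 in the other 5. Of 20 genes of injury-activated Schwann cells, 6 rose, 4 fell and 10 were not called (6 and 5 adjusted over the list alone; camera adjusted p = 0.30). The neural adhesion molecule Ncam1 (1.33), Runx2 (1.29) and Tnfrsf12a (1.06) rose and L1cam fell by 0.91, while Gap43 (0.21), Gfap (0.16) and Ngfr (-0.13) were not called.

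Of 47 genes of neurons and axons, 10 fell, 4 rose and 33 were not called (10 and 4 adjusted over the list alone). Camera did not call the list (adjusted p = 0.209), whereas fry, which does not compare it with other genes, called it lower (adjusted p = 0.00498). Its means were -0.29 to -0.10 in the denervated arrays and -0.04 to 0.07 in the sham arrays. After Nefl, Stmn2 (-1.21 ± 0.12), a neuronal regulator of microtubules, and the synaptic vesicle protein Syt1 (-1.21 ± 0.21) fell most, and Tubb3, neuronal tubulin, rose by 1.34 ± 0.32. Tubb3 was dim, with group means of 4.24 (sham) and 5.58 (denervated) below the array medians. Denervated replicate 2 (4.10) lay within its sham range, and the call of Tubb3 was lost with the exact rank-sum test (adjusted p = 0.116). Ddc, an enzyme of catecholamine synthesis, fell by 0.73, and Th (-0.22), Chat (0.03), Vip (-0.09) and Calca (-0.26) were not called. Of 28 neurotrophic and axon guidance factors, 5 rose, 7 fell and 16 were not called (5 and 7 adjusted over the list alone), and 8 rose without denervated replicate 2. Neurotrophin 3 (Ntf3, -1.37 ± 0.17) and Sema3a (-1.09 ± 0.21) fell, and Sema3d (1.59 ± 0.26) and pleiotrophin (Ptn, 1.27 ± 0.12) rose. That list was not called (camera adjusted p = 0.917), and its median of -0.08 differed in sign from its mean of 0.0005 and from the direction of the test, which was up.

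Among smooth muscle genes more fell than rose. Of 26 genes of the contractile apparatus, 15 fell, 3 rose and 8 were not called (18 and 3 adjusted over the list alone; camera adjusted p = 0.000868, and adjusted p = 0.481 with an estimated correlation). The myosin phosphatase inhibitor Ppp1r14a fell by 1.21 ± 0.21, Pdlim3 by 1.00 ± 0.16, myosin light chain kinase (Mylk) by 0.99 ± 0.14 and the transcriptional coactivator Myocd by 0.89 ± 0.21. The call of Myocd was lost with the exact rank-sum test (adjusted p = 0.116) and with the test against 1.2-fold (0.0748). Smooth muscle myosin heavy chain (Myh11) fell by 0.51 ± 0.11, or 1.42-fold. The abundant structural genes Actg2 (-0.01 ± 0.09, adjusted p = 0.943) and Des (-0.10 ± 0.07, adjusted p = 0.342) were not called, and Des was called lower (-0.20, adjusted p = 0.0227) after a further quantile normalization. The integrin subunit Itga8 rose by 2.60 ± 0.35, and Sync (0.93) and Smtn (0.51) rose too. The list's mean was -0.52 and -0.59 in denervated replicates 5 and 6, -0.20 to -0.08 in the other 4 and -0.09 to 0.11 in the sham arrays. Actb, a common reference gene, was not called (-0.05 ± 0.05, adjusted p = 0.480).

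Ion channel and calcium handling genes of smooth muscle had 18 of 39 members lower, 5 higher and 16 not called (18 and 6 adjusted over the list alone; camera adjusted p = 0.0240, and adjusted p = 0.458 with an estimated correlation). The call was lost without denervated replicate 6 (adjusted p = 0.0588). The list's mean was -0.01 in denervated replicate 2, within the -0.06 to 0.05 of the sham arrays, and -0.43 to -0.19 in the other denervated arrays. Phospholamban (Pln, -1.21 ± 0.19), the ryanodine receptor Ryr3 (-1.20 ± 0.27) and the calcium channel Cacna1h (-0.93 ± 0.18) fell, and connexin 43 (Gja1) rose by 1.62 ± 0.25. Ryr3 lost its call with the exact rank-sum test (adjusted p = 0.158), and in denervated replicate 2 (8.38) it lay above every sham value. Of 10 caveolae genes, 5 fell, 0 rose and 5 were not called (5 and 0 adjusted over the list alone; camera adjusted p = 0.0409, and adjusted p = 0.320 with an estimated correlation). This call was lost when any of sham replicates 1, 4 and 5 or denervated replicates 1, 2, 5 and 6 was left out, and with a further quantile normalization, array weights or the brighter genes only, with adjusted p of up to 0.0737. There were 3 falls when any of sham replicates 1, 2, 4 and 5 or denervated replicates 4 and 5 was left out. Pacsin2 (-0.39), Cavin2 (-0.38), Cavin1 (-0.29), Pacsin3 (-0.25) and caveolin 1 (Cav1, -0.16 ± 0.05) fell. The call of Pacsin3 was lost without any of sham replicates 1, 2, 4 and 5 or denervated replicates 3, 4 and 5 (adjusted p up to 0.0648), and that of Cav1 without any of sham replicates 1, 2, 4 and 5 or denervated replicates 4 and 5 (up to 0.0695) and after a further quantile normalization (0.0533).

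Receptors for transmitters and peptides changed in both directions. Of 28 such genes, 8 fell, 7 rose and 13 were not called (11 and 8 adjusted over the list alone; camera adjusted p = 0.901). The rises numbered 4 without sham replicate 2 or 6 or denervated replicate 4 or 5, and 5 fell without sham replicate 1 or denervated replicate 3. The muscarinic receptor Chrm2 fell by 0.56 ± 0.12, and Chrm3 fell by 0.38 ± 0.12 with a call that was lost without sham replicate 1 (adjusted p = 0.0573), 5 (0.0529) or 6 (0.0582) or denervated replicate 3 (0.0531). The purinergic receptor P2rx1 fell by 0.78 ± 0.17 and the beta-3 adrenoceptor Adrb3 by 1.07 ± 0.18, whereas the serotonin receptor Htr2a rose by 1.34 ± 0.31 and P2rx4 by 0.85 ± 0.18.

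Mitochondrial genes fell. Of 34 respiratory chain genes, 28 fell, 0 rose and 6 were not called (28 and 0 adjusted over the list alone; camera adjusted p = 1.62e-10, and adjusted p = 0.170 with an estimated correlation). The list had a median of -0.28, with Ndufs7 (-0.52 ± 0.07), Ndufs1 (-0.51 ± 0.08), Cox6c (-0.50 ± 0.09) and Sdha (-0.47 ± 0.08) lowest. Of 39 genes of fatty acid oxidation and the citrate cycle, 24 fell, 0 rose and 15 were not called (28 and 0 adjusted over the list alone; camera adjusted p = 1.25e-09, and adjusted p = 0.170 with an estimated correlation). Ppargc1a, a coactivator of mitochondrial genes, fell by 1.65 ± 0.14, the citrate cycle enzyme Idh2 by 0.98 ± 0.15, Pdk2 by 0.68 ± 0.14 and Ppara by 0.64 ± 0.14. Glycolysis and hypoxia genes showed no common direction, with 8 of 27 higher, 8 lower and 11 not called (9 and 10 adjusted over the list alone; camera adjusted p = 0.917). There Egln3 fell by 0.98, Pfkm by 0.59 and Slc16a1 by 0.57, and the carbonic anhydrase Car9 rose by 0.93. The median (-0.11) and mean (-0.05) of that list were below 0 while the test's direction was up.

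Markers of the urothelium were lower. Of 35 urothelial genes, 28 fell, 1 rose and 6 were not called (29 and 1 adjusted over the list alone; camera adjusted p = 2.36e-11, and adjusted p = 0.219 with an estimated correlation). Besides Krt20, the epithelial transcription factor Grhl3 fell by 0.88 ± 0.11, Psca by 0.87 ± 0.11 and the uroplakin Upk3a by 0.49 ± 0.07. Krt14, a keratin of basal epithelial cells, rose by 1.35 ± 0.36, and 2 members rose without denervated replicate 2. In denervated replicate 2 the mean over the list was -0.37, within the -0.68 to -0.35 of the other 5.

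Secreted regulators of growth moved in both directions. Of 39 genes of TGF-beta and BMP signalling, 16 rose, 11 fell and 12 were not called (16 and 14 adjusted over the list alone), and the list was not called (camera adjusted p = 0.103), except among the brighter genes only (0.0402) and by fry (0.0436). Its median was -0.01 while its mean of 0.28 and its test pointed up. After Grem1, the latent TGF-beta binding protein Ltbp2 (2.76 ± 0.43), Tgfb3 (1.72 ± 0.29) and the activin subunit Inhba (1.59 ± 0.29) rose. Of 39 Wnt signalling genes, 6 rose, 13 fell and 20 were not called (8 and 14 adjusted over the list alone; camera adjusted p = 0.515). Of the secreted Wnt antagonists, Sfrp4 (2.60 ± 0.37), Sfrp1 (1.57 ± 0.29) and Dkk3 (1.04 ± 0.17) rose and Sfrp2 (-0.45), Dkk2 (-0.39) and Sfrp5, which is not in the list, fell, and the receptor Lgr5 fell by 1.19 ± 0.20. Of 43 growth factors and members of the insulin-like growth factor axis, 13 rose, 13 fell and 17 were not called (16 and 13 adjusted over the list alone; camera adjusted p = 0.246), with a median of -0.0014 and a mean and a test above 0. Igf1 rose by 1.25 ± 0.16 or 2.38-fold, its binding protein Igfbp3 fell by 1.49 ± 0.23, Vegfd rose by 2.40 ± 0.30 and Fgf1 fell by 0.92 ± 0.13. In denervated replicate 2 Igf1 stood at 10.89, against 11.62 to 12.03 in the other 5.

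Of 40 stretch, SRF and YAP target genes, 12 rose, 4 fell and 24 were not called (13 and 4 adjusted over the list alone; camera adjusted p = 0.0327, and adjusted p = 0.536 with an estimated correlation). This call was lost without sham replicate 5 (adjusted p = 0.0548), denervated replicate 3 (0.0782) or denervated replicate 5 (0.0506), and with fry (0.137). The mean over the list was -0.09 in denervated replicate 2, 0.06 to 0.34 in the other denervated arrays and -0.08 to 0.04 in the sham arrays. Nonmuscle myosin Myh10 (1.13 ± 0.18), Tpm4 (0.88 ± 0.16), Fhl3 (0.87 ± 0.12) and the receptor kinase Axl (0.85 ± 0.14) rose, whereas Ankrd1 (0.03) was not called and Srf itself fell by 0.48. Of 27 immediate early genes, 4 rose, 2 fell and 21 were not called (3 and 1 adjusted over the list alone; camera adjusted p = 0.0409, and adjusted p = 0.605 with an estimated correlation). Leaving out any of sham replicates 1, 3 and 5 or denervated replicates 3, 5 and 6 ended this call, with adjusted p of up to 0.0984, as did testing the brighter genes only (0.0630) or fry (0.256). The mean over the immediate early genes was -0.11 and -0.17 in denervated replicates 1 and 2 and 0.13 to 0.34 in the other denervated arrays. Sham arrays spanned -0.16 to 0.14. Socs3 rose by 0.47 and Klf2 by 0.49, the latter with a call that was lost when any array other than sham replicate 4 and denervated replicate 2 was left out (adjusted p up to 0.0933), Rgs1 fell by 1.07, and Fos (0.02) and Jun (0.18) were not called. Without denervated replicate 2, 6 rose, and 1 fell without any of sham replicates 2, 3, 4 and 6 or denervated replicates 1, 2, 3, 4 and 6.

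The senescence and apoptosis list had 5 of 18 members higher, 2 lower and 11 not called (5 and 2 adjusted over the list alone; camera adjusted p = 0.0409, and adjusted p = 0.235 with an estimated correlation). The list call was lost without sham replicate 3 or 6 or denervated replicate 5, with adjusted p of up to 0.0573, and with the brighter genes only (0.0716), and 4 members fell without denervated replicate 2. The cell cycle inhibitor Cdkn2b (0.97), the inflammatory caspase Casp1 (0.89) and Casp12 (0.65) rose, as did Casp4 (0.75), whose call was lost without sham replicate 2 (adjusted p = 0.0530) or 6 (0.0520). Of 17 heat shock and RNA quality genes, 3 rose, 1 fell and 13 were not called (3 and 1 adjusted over the list alone; camera adjusted p = 0.653), with a median of -0.06 and a mean and a test above 0. Heme oxygenase (Hmox1, 1.37 ± 0.14), Gadd45b (1.27) and Gadd45g (0.84) rose and the small heat shock protein Hspb8 fell by 0.91. Without sham replicate 1 or denervated replicate 4 or 5, 2 members fell, and without denervated replicate 6, 3. Of 26 genes of atrophy, autophagy and the proteasome, 3 rose, 1 fell and 22 were not called (3 and 1 adjusted over the list alone; camera adjusted p = 0.985), with the median and mean below 0 and the test's direction up. The muscle ubiquitin ligase gene Fbxo32 fell by 0.81 and the lysosomal genes Ctsl (0.52), Ctsb (0.51) and Lamp2 (0.19) rose. There 2 members fell without sham replicate 1 or denervated replicate 2, and 4 without denervated replicate 6.

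Of 23 adipocyte genes, 8 fell, 1 rose and 14 were not called (8 and 1 adjusted over the list alone; camera adjusted p = 0.196). The lipogenic gene Thrsp fell by 1.87 ± 0.38, Plin4 by 0.85 and Cidea by 0.80, the complement protease Cfd rose by 1.34, and Adipoq (-0.24) was not called. Without denervated replicate 3, 2 adipocyte genes rose. Of 23 skeletal muscle genes, 3 rose, 2 fell and 18 were not called (4 and 4 adjusted over the list alone; camera adjusted p = 0.782), with the median and mean below 0 and the test's direction up, and 5 rose and 3 fell without denervated replicate 2. Without sham replicate 4 or denervated replicate 5, 4 fell. Skeletal actin (Acta1) rose by 1.56 ± 0.29, muscle creatine kinase (Ckm) fell by 1.07 and Tnnc2 by 0.78. Actn2 rose by 0.33, with a call that was lost without any of sham replicates 2, 3, 5 and 6 or denervated replicate 5 (adjusted p up to 0.0664). Of 10 red blood cell genes, 9 were not called, and the transferrin receptor Tfrc rose by 0.33, a call lost without any of sham replicates 1, 2, 3, 4 and 6 or denervated replicates 3, 5 and 6 (adjusted p up to 0.0882) and when adjusted over the list alone (0 and 0; camera adjusted p = 0.531). Of 16 circadian clock genes, 3 rose, 6 fell and 7 were not called (4 and 6 adjusted over the list alone; camera adjusted p = 0.515), and fry called this list lower (adjusted p = 0.0104). The clock repressor Nr1d1 fell by 1.29 ± 0.17 and Rora by 0.45, and Bhlhe40 (0.92 ± 0.14) and Per2 (0.48) rose.

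**Figure D3:**
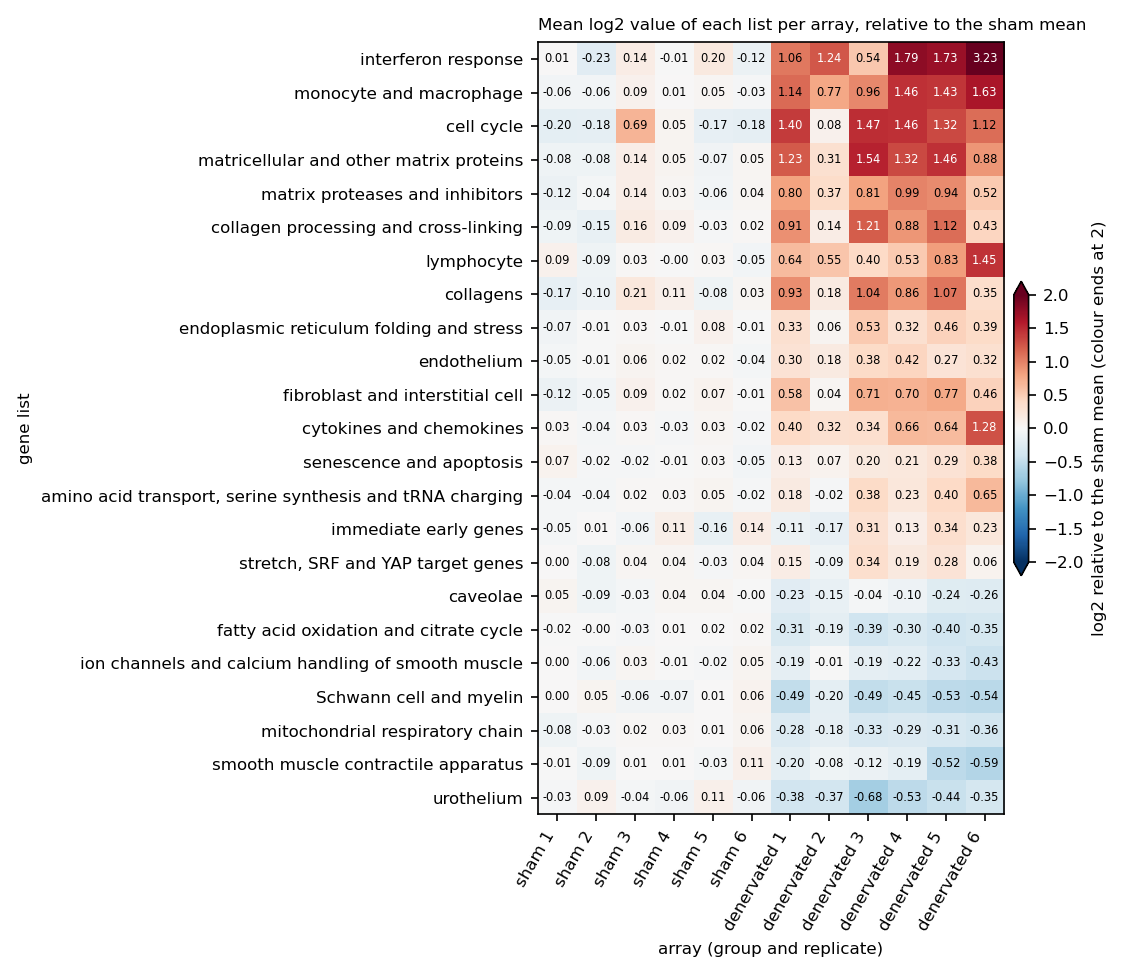
For each of the 23 called gene lists (vertical axis) and each of the 12 arrays (horizontal axis), the colour and the printed number give the mean log2 value of the list's members relative to the mean of the 6 sham arrays. Denervated replicate 2 stood at 0.08 for the cell cycle and 1.24 for the interferon response, and sham replicate 3 stood at 0.69 for the cell cycle.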

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

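The tests of the pattern in denervated replicate 2, of the immune and endothelial lists and of the urothelium list were chosen only after those results were seen, and the count of regroupings was fixed before.

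Whether the split of the 12 arrays into denervated and sham could be matched by other splits was tested on 100 of the 462 possible splits into 6 and 6. Of these, 1, the real one, gave as many as 5216 called genes, and 93 gave 0 genes past the limma threshold. The highest other split, which exchanges sham replicate 3 and denervated replicate 2, gave 3929 genes. A count of this size was thus not reached by regrouping the arrays, while nothing here can separate the operation from an unrecorded array batch that followed it.

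The gap of the most extreme array to its nearest neighbour, divided by the range of its group, was computed for 442 groups of 6 arrays. Chance marks about 1 in 20 such groups, or 22.1 here, and 41 were marked, 23 of them in denervated replicate 2. On the first principal component the share of the range was 0.657 both for denervated replicate 2 and for sham replicate 3, which lay toward each other's group. For denervated replicate 2 the share was 0.746 for the mean over cell cycle genes and 0.726 for that over Schwann cell and myelin genes. Among single genes it lay below the rest of its group in Grem1 (0.663), Lox (0.636), Loxl1 (0.690), Eln (0.694), Mki67 (0.678), Top2a (0.757), Sdf2l1 (0.786), Lyz2 (0.666), S100a8 (0.658), Vegfd (0.717), Igf1 (0.640) and Ctsl (0.686). It lay above the rest in Pla2g2a (0.634), Cdh19 (0.726), Car14 (0.766), Ryr3 (0.655), Ppargc1a (0.664), Idh2 (0.647), Ntf3 (0.70) and Igfbp3 (0.664). On each of these 20 genes it lay on the side of the sham arrays.

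Denervated replicate 2 lay nearer to the mean of the sham arrays than to that of the other denervated arrays, with a median correlation of 0.988 with sham arrays and 0.979 with denervated ones. A sham bladder carrying the wrong label would have its macrophage mean among the sham arrays, but denervated replicate 2 lay 13.2 SD of the sham arrays above them. That list was picked after this array had been seen to lie away from the sham arrays in it. The array's cell cycle mean (0.08) lay within the sham range of -0.20 to 0.69, and its interferon response mean (1.24) outside that of -0.23 to 0.20. Sham tissue or RNA mixed into the sample would give macrophage and cell cycle genes the same fitted share of denervated tissue, and these shares differed by at least 0.173 (95% bootstrap interval over genes 0.0887 to 0.273) with each of the other 5 arrays as partner, but the interval for a further partner was -0.127 to 0.891, so a mixture stays open. A response smaller by the same factor throughout stays open too: the least-squares slope, through 0, of the members' changes in this array on their mean changes in the other 5 was higher for macrophage than for cell cycle genes by 0.475 (bootstrap interval over genes 0.387 to 0.561), and denervated replicate 6, set against the remaining 4, had 0.544. A difference between animals, such as in the extent of denervation, might also give this pattern, and no biological explanation was tested, since the labels give no group within the denervated bladders.

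Camera called the macrophage, lymphocyte and endothelial lists higher in a tissue labelled as almost wholly smooth muscle, with 25 of 28, 19 of 29 and 12 of 25 members higher, but not with an estimated correlation (adjusted p = 0.170, 0.211 and 0.170). A lower share of smooth muscle with no change in the other cells would raise the markers of every other cell type alike. The macrophage list had a median of 1.38 and the urothelium list one of -0.46, the highest and lowest of the cell type lists compared. They lay 1.84 apart (95% bootstrap interval over genes 1.57 to 1.98), but both medians had been seen before, so this test adds nothing to them. Medians of opposite sign are not what this explanation alone would give. Of the 25 macrophage genes brighter than the median gene 92.0% rose, but this decides nothing about more macrophage RNA in the tissue, since the count over the whole list had already fixed it. Whether there were more such cells or more RNA from the cells present stays open.

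Camera called the urothelium list lower, though not with an estimated correlation (adjusted p = 0.219), and dilution of an unchanged urothelium by other tissue could give all members the same fall. The 95% intervals of 12 of the 35 members left out the list's median, which is more than 5% of intervals would by chance. The exact binomial p was 6.90e-08 (two-sided), in a test that treats the members as independent although they share the same arrays. At face value the changes thus differed in size between members. This cannot decide on uniform dilution, since probes that respond unequally to the same change could also spread the falls. Falls were larger than the median in Krt20, Upk2, Psca, Grhl3, Rab27b and Cldn8, and smaller, or turned to a rise as in Krt14 (1.35), in Krt13, Krt14, Krt15, Krt17, Pkp1 and Sprr1b. Unequal response of probes would not turn a fall into a rise. The rise of Krt14 is limited, however, since in denervated replicate 2 (6.45) it lay within the sham range of 5.82 to 7.48. Its call was lost with the exact rank-sum test (adjusted p = 0.0576) and with the test against 1.2-fold (0.0703). A shift from superficial to basal urothelial cells stays open as an untested hypothesis.

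Sham replicate 3 lay above the rest of the sham arrays in the mean over cell cycle genes (0.719), in Ckap2 (0.655) and in Top2a (0.640). Denervated replicate 6 lay above its group in the mean over cytokines and chemokines (0.649), in Cd8b (0.690), Casp1 (0.644) and Casp4 (0.706). In sham replicate 6 Ppp1r14a (0.687) and Mylk (0.688) lay highest, and in sham replicate 5 Amd1 (0.717) and Upk3a (0.640) lay highest and Pdk2 lowest (0.659). Sham replicate 2 lay lowest in the mean over glycolysis and hypoxia genes (0.667), in Runx2 (0.712) and in Ly6c (0.634). Sham replicate 4 lay lowest in Socs3 (0.697) and sham replicate 1 in Per2 (0.722).

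Among the 17599 probe sets without a gene name, which the comparisons by gene leave out, 1249 passed the threshold, 600 higher and 649 lower in denervated bladders, 248 of them by at least 2-fold.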

How the results depend on the processing

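The counts without single arrays for the members of each list were chosen only after the result was seen, and all other alternatives were fixed before. Against a change of 1.2-fold, 756 genes were higher and 496 lower instead of 2153 and 3063, because that test leaves out small changes. Among genes brighter than the median gene, 310 rather than 527 were higher by at least 2-fold, as fewer genes were tested. With an estimated correlation camera called 0 lists higher and 0 lower. For every list called with the preset correlation of 0.01, the estimate lay above that preset. These estimates ran from 0.0376 for senescence and apoptosis to 0.857 for the interferon response, with 0.494 for macrophage and 0.706 for cell cycle genes. Whether the higher correlations alone ended the calls was not tested. The fry test, which asks another question, left the amino acid transport, stretch target and immediate early lists uncalled and called the neuron, TGF-beta and circadian lists. Leaving out single arrays gave 1831 to 2612 genes higher and 2543 to 3661 lower, with the highest counts (6273 in all) without denervated replicate 2. Other scalings, variance models and weights kept each of these counts within 1.5 times of its reported value, and 4957 of the 5216 calls were kept with the further quantile normalization and 5085 with median centring. Actg2, not called, turned to 0.0571 with array weights and ranged from -0.0542 (without denervated replicate 4) to 0.0357 (without denervated replicate 2) when single arrays were left out, and the cause was not tested. Among all combinations of a named gene with an alternative, 67 lost a call, 1 gained a call and 1707 did neither, and among those with a single array left out 45 lost a call and 2123 kept theirs or stayed uncalled, the rest being those of Actg2. The exact rank-sum test ended the calls of Col8a1 and Tnfrsf12a (adjusted p = 0.116 each), among others. The replicate numbers did not pair the samples: deviations of same-numbered arrays correlated at -0.11 to 0.10, and 1 of 6 sham arrays correlated best with its own number. With the replicate block 1984 genes were higher and 2476 lower, and 16 lists were called higher and 6 lower, caveolae (adjusted p = 0.0725) losing its call. Detection calls were not used here, so the signal over background of dim genes is unknown.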

Other observations

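The gene groups in the next paragraphs were put together only after single members had been seen, except that the test of the aryl hydrocarbon receptor's other target genes was fixed before their values were seen. The p-values of the groups are therefore descriptive only. They are adjusted over the groups of this part alone and cannot be set against those of the lists fixed beforehand.

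Genes of the complement system rose in the denervated bladders. Of 15 such genes, 12 rose and 0 fell (13 and 0 adjusted over the list alone; camera adjusted p = 2.73e-11 over the 6 lists of this part, and adjusted p = 0.0297 with an estimated correlation). C3ar1, a receptor for a fragment of C3, rose by 2.53 ± 0.24, C3 by 2.18 ± 0.27, C6 by 1.70 ± 0.26 and C1qa by 1.32 ± 0.15, whereas C7 (-0.04) and Clu (-0.09) were not called. C1qa, C1qb and C1qc are also in the macrophage list, C3 in the fibroblast list and Cfd in the adipocyte list.

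Enzymes that conjugate foreign compounds fell. Of 20 genes, 15 fell and 0 rose (15 and 0 adjusted over the list alone; camera adjusted p = 1.63e-06, and adjusted p = 0.0297 with an estimated correlation). The sulfotransferases Sult1a1 (-1.72 ± 0.31) and Sult1d1 (-1.39 ± 0.20) and the glutathione transferases Gstm7 (-1.58 ± 0.20) and Gsta4 (-0.93 ± 0.24), the latter of families with close copies, fell most. Of 16 fatty acid synthesis genes, 10 fell and 0 rose (13 and 0 adjusted over the list alone; camera adjusted p = 2.51e-05, and adjusted p = 0.0413 with an estimated correlation), among them Scd (-3.01), Thrsp (-1.87), Elovl6 (-0.50) and Gpam (-0.46). Thrsp, Elovl6 and Dgat2 are also in the adipocyte list, and Scd and Thrsp had been seen to fall before the list was written. Of 18 cholesterol synthesis genes 3 fell and 0 rose (3 and 0 adjusted over the list alone; camera adjusted p = 0.632). Among 19 genes of the cyclic GMP pathway, through which nitric oxide relaxes smooth muscle, 7 fell and 4 rose (8 and 4 adjusted over the list alone; camera adjusted p = 0.181). There the phosphodiesterases Pde5a (-1.52 ± 0.22) and Pde9a (-1.44 ± 0.25) fell.

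Cyp1a1 (-2.33) and Ahrr (-1.09), both targets of the aryl hydrocarbon receptor, fell, and the hypothesis that target genes of this receptor fell together was tested on the other listed targets. Of the other 6, 2 fell, Aldh3a1 (-1.10 ± 0.15) and Scin (-0.67 ± 0.09), while Cyp1b1 (0.22), Nqo1 (-0.33), Cyp2s1 (-0.11) and Nfe2l2 (-0.18) were not called. This falls short of the 50% set beforehand, while over all genes 3063 of 18166 fell. The count cannot decide against a common fall of these targets, since it takes few genes and treats an uncalled change as none. Among the uncalled ones only Cyp1b1 lay above 0. The whole list of 8, which includes the genes that prompted it, had 4 lower and 0 higher (4 and 0 adjusted over the list alone; camera adjusted p = 0.00185, and adjusted p = 0.0297 with an estimated correlation).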
